A study of Caenorhabditis elegans with 2 samples.

How the data were processed

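CEH-9, a homeodomain protein of the nematode Caenorhabditis elegans, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole L3 larvae of strain OP202. The strain carries a transgene that expresses CEH-9 with a C-terminal GFP-FLAG tag in an unc-119 mutant background. Per the labels, the chromatin came from larvae of both sexes and was sheared by sonication. The 2 samples form 1 group, with biological replicates 1 and 3, each with 1 technical replicate. The labels name ceh-9 as the target, while their free-text description calls both libraries input. The samples were treated as CEH-9 ChIP because the assay, antibody and file types say so, and this conflict stays open.

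Per the deposited descriptions of the files, the authors called peaks and background regions on each replicate alignment against a control alignment, and again on the pooled replicates. The ce11 lists of both replicates were called against the same control alignment. A set of peaks that passed a threshold of the irreproducible discovery rate (IDR) was then derived by the authors from both replicate lists and the pooled list, and it is called the reproducible set here. The aligner, the peak caller, its scaling and the IDR threshold are not given in the sources used here. Column 7 of the deposited lists holds the caller's signal value for a region, which has no stated unit and was used only to rank and describe regions within a list. Column 9 holds the −log10 of a q-value, per the narrowPeak format that the deposited descriptions name. The column for an unadjusted p-value held a placeholder in every region. The point of strongest signal, the summit, lay at the middle of every region except 1 in the replicate 1 list. Read depths and control values were not analysed here, so neither a depth nor a fold over control is given. All p-values concern positions in these 2 libraries.

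The lists were deposited on builds ce11 and ce10. The ce11 lists were compared with the WBcel235 genome, and every region ended within its chromosome. Gene annotation came from Ensembl release 115 of the same build. Coordinates are 1-based on ce11, and none was converted between builds. The ce10 lists entered only counts, signal values and replicate comparisons.

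The following choices were made before the data were examined. Regions counted as matched when their summits lay within 200 bp. The 1000 strongest regions of replicate 1 were compared with the 1000 strongest of replicate 3, and with 1000 circular shifts of the replicate 3 summits along each chromosome (one-sided permutation test). Signal values of matched regions were compared by Spearman's rho with 100000 permuted pairings (two-sided). A promoter window ran from 1000 bp upstream to 200 bp downstream of any annotated transcript start. The share of summits in such windows, in 4 other feature classes and inside non-coding RNA genes was compared with 10000 sets of random positions on the same chromosomes (two-sided permutation test). The content of the non-coding class was settled only after another version had been run, and both are reported. Counts per chromosome were compared with chromosome lengths by a chi-square statistic over 100000 multinomial draws. Sequence words were counted on both strands within 100 bp of the summit. The comparison set was weak regions, those with a pooled signal value below the list's median, drawn at 10 per peak from the same chromosome (Fisher's exact test, two-sided). The 8 words were adjusted together by the Benjamini-Hochberg method. ATTTAA and TTAAAT are reverse complements of each other, so 2 of the 3 control words gave the same counts. Genes with a reproducible summit in a promoter window were compared between 19 gene lists and all genes of the same class, coding or non-coding (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over lists). The lists were homeobox, nuclear hormone receptor, bHLH and other transcription factors, neuropeptides, pan-neuronal genes, ribosomal proteins, translation factors, collagens and cuticle, muscle, intestine, germline, histones, heat shock, tRNA, snRNA, snoRNA, rRNA and miRNA. Signal near ceh-9 and unc-119 was ranked among 10000 random windows of the same size, reaching 20 kb to either side. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. The threshold was 0.05.

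The named genes were those with the annotated start nearest to each of the 25 strongest reproducible peaks within 5000 bp, transcription factor list genes with a reproducible peak in a promoter window, 2 to 4 members of other lists that passed the test, and ceh-9 and unc-119. Other genes are named only where a count is 5 or fewer or a feature is singled out, and these were chosen after their values were seen. Alternatives changed 1 choice at a time: the number of regions, the matching distance, the window size, the background, a stricter set at or above the median signal, the other build, and each replicate left out. Protein-coding starts were also combined with the weak background, and words in the 500 strongest regions were compared with all 5244 weak regions. Where 1 replicate was left out, the set was the 45 strongest nuclear regions of the remaining replicate, since no reproducible set can be made from 1 list. Mitochondrial regions were left out of that set after they had been seen in replicate 1. At the transgene loci, the whole list of the remaining replicate was used instead. The tests were run on 100 simulated data sets with 1000 regions (overlap) or 45 regions (promoter, chromosome and word shares). These runs used fewer shifts and draws than the main tests, and random positions in place of weak regions. Sets with no effect passed the threshold in 1%, 4%, 8% and 2% of runs, in that order, and planted effects (4% shared regions, a promoter share of 70%, an X share of 50%, and a word placed in 14 of the 45 windows) were detected in 100% of runs at each step. The planted promoter share was above the 55.6% found in the data, so detection at that size was not measured. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.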

Results

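Binding of CEH-9, a homeodomain protein, was profiled by ChIP-seq in L3 larvae that carried a GFP-FLAG-tagged copy of the protein. There was 1 group of 2 biological replicates, numbered 1 and 3, and no second group, so the comparisons are between replicates and between the peaks and the rest of the genome. The labels describe both libraries as input in one field and as CEH-9 ChIP in the others. The list of each replicate held 30000 regions on build ce11, the pooled list 10489 and the reproducible set 45. Replicate lists of this length contain background: 3048 regions of replicate 1 and 24 of replicate 3 had a q-value under 0.05. The highest signal value was 80.1 in replicate 1 (a mitochondrial region; 43.6 in its strongest nuclear region), 30.2 in replicate 3 and 72.9 in the pooled list. Read depth is unknown here.

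The first question was where the peaks of the authors' reproducible set lay. Signal values given for them are those of the pooled replicates, and support in replicate 3 was uneven. Of the 45 peaks, 40 had a region within 200 bp in replicate 3, at a median rank of 1854.5, and 15 had one among its 1000 strongest. The strongest reproducible peak, on chromosome X from 14525711 to 14526026, had a signal value of 72.9 and lay 688 bp upstream of nspc-17 (WBGene00008359), a gene of a nematode-specific peptide family. The next, on X from 11094026 to 11094341 with a signal value of 63.0, was intergenic, and the nearest start was that of a tRNA gene (WBGene00014538) 1489 bp away. An intergenic peak on X from 4209133 to 4209448 had a signal value of 60.3, with F20B6.9 as the nearest gene, and another on X from 13700741 to 13701056 had 52.3, nearest to the non-coding RNA gene K02D3.5. Further strong X peaks lay nearest to the F-box gene fbxb-58 (signal value 51.1), the non-coding RNA gene C30E1.9 (49.1), F22H10.2 (44.8), a tRNA gene (WBGene00023117, 44.7), the non-coding RNA gene F52D10.12 (43.8), cest-16 (40.8) and K03A1.9 (39.6). The F52D10.12 peak also lay 453 bp upstream of ftt-2, which encodes a 14-3-3 protein. The cest-16 peak lay inside an intron of mom-1, a gene of Wnt secretion.

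Among the 25 strongest peaks, those outside this run on X were nearest to the snoRNA gene ZK994.7 on chromosome V (signal value 38.7), cel-mir-53 on IV (37.2), ZK265.13 on I (36.4), Y52B11B.1 on I (36.2, within hmr-1, a cadherin gene), C16C2.7 on I (35.2, in the promoter window of eat-16), a non-coding RNA gene on IV (WBGene00201963, 34.98), sqv-6 on V (34.9) and T26E3.4 on I (34.3). A tRNA gene (WBGene00023111, 38.3), T10B10.11 (37.7), gtr-1 (35.2) and pdk-1 (33.4), which encodes a phosphoinositide-dependent kinase, were nearest to the remaining X peaks of the 25. Both peaks on chromosome III among the 25 lay at zfp-1, a chromatin factor gene. One was in an intron from 8795699 to 8796014 (34.6) and one in a promoter window from 8801995 to 8802310 (34.3). Of the 25 nearest starts, 12 belonged to protein-coding genes and 13 to non-coding ones. The 45 reproducible peaks were the 45 strongest regions of the pooled list, with signal values from 30.7 to 72.9. Of these, 28 had a q-value under 0.05, and the largest q-value was 0.147.

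Chromosome X carried 22 of the 45 reproducible peaks, or 48.9% (95% interval 33.7 to 64.2), where its length would give 7.95. The 11 strongest peaks were all on X. Chromosome I had 7 peaks, V had 6, IV had 5, III had 3 and II had 2. Of the 23 autosomal peaks, 13 (56.5%) lay in the central part of their chromosome when its length is cut into 3 equal parts, where weak autosomal regions had 35.5%. The counts departed from chromosome length (permutation p = 1e-05, the smallest that 100000 draws can give). The median signal value was 38.97 for the 22 X peaks and 32.8 for the 23 autosomal peaks. The X peaks spanned 16.5 Mb of the 17.7 Mb chromosome. The X share was 23.2% at ranks 46 to 200 of the pooled list and 19.7% in its weak regions. At a cut of the 45 strongest nuclear regions, the excess was seen in replicate 1, where X held 22 of the 45. In replicate 3, X held 9 of 45 (20%, 95% interval 9.58 to 34.6), and the counts did not depart from chromosome length (permutation p = 0.68). Only 24 regions of replicate 3 had a q-value under 0.05, so its 45 strongest include regions that did not. Of the 22 reproducible X peaks, 9 (40.9%) nonetheless lay within 200 bp of one of the 1000 strongest regions of replicate 3, with ranks 1, 3, 4, 7 and 15 the highest.

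**Figure D1:**
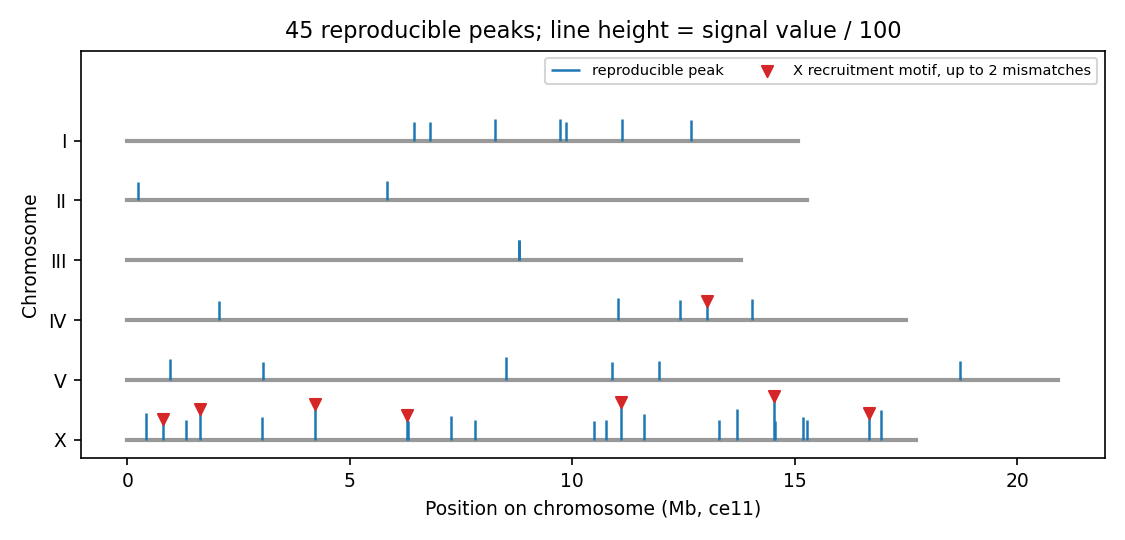
Positions of the 45 reproducible peaks on the nuclear chromosomes (horizontal axis, Mb on ce11), where the height of each line is the peak's signal value and triangles mark peaks with the X recruitment motif described in the closing section. X carries 22 of the 45 peaks and 7 of the 8 marked ones.

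Reproducible peaks were compared with gene structure to ask whether they lay at promoters. Summits of 25 of the 45 peaks (55.6%, 95% interval 40 to 70.4) lay in a promoter window, against 37.2% of random positions (permutation p = 0.0174). Named examples were nspc-17, T26E3.4, with its start 26 bp from the summit, zfp-1, cel-mir-53, and nhr-49, which encodes a nuclear hormone receptor of fat metabolism. Of the other summits, 9 lay in introns, 8 in intergenic sequence, 2 in exons and 1 downstream of a gene. Exons outside promoter windows held 4.44% of the reproducible summits and 20.3% of random positions (permutation p = 0.0056, adjusted p = 0.0168 over 6 feature classes). Promoter windows were assigned before exons, introns, downstream and intergenic sequence. A higher promoter share therefore leaves fewer summits for exons, and summits in exons within promoter windows are not in the exon count. Non-coding RNA genes held 6 summits (13.3%, against 2% of random positions, permutation adjusted p = 0.0072). This class was counted apart from the others and overlaps them. These 6 summits also lay in promoter windows, so the non-coding and promoter calls share peaks. Windows of protein-coding starts held 15 summits (33.3%), against 24.4% of random positions (permutation p = 0.217). The promoter call was also lost with either replicate left out (40% without replicate 1, 51.1% without replicate 3), in the stronger 23 peaks (47.8%), and with windows 2000 bp upstream (68.9% against 56.2%). The promoter p adjusted over 6 feature classes was 0.0348. When the non-coding class took in pseudogenes and left out piRNA genes, the version run before the present one, the adjusted p was 0.0522 for promoters, 0.0336 for exons and 0.0576 for that class (permutation), so the promoter and non-coding calls depend on this definition. Against weak regions, the promoter p adjusted over 5 classes was 0.114 (Fisher's exact test).

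Of 19 gene lists, only the tRNA genes passed the test. Reproducible peaks lay in the promoter windows of 9 of 634 tRNA genes, against 0.682 expected from all non-coding genes (Fisher's exact test, adjusted p = 2.61e-07). On chromosome X these included WBGene00023117 (410391 to 410462, signal value 44.7) and the adjacent pair WBGene00023111 and WBGene00023110 (3035976 to 3036235, 38.3). On V, WBGene00023221 (8499564 to 8499636) shared a peak with the snoRNA gene ZK994.7 (38.7). Since neighbouring genes share a peak, the 9 genes corresponded to 5 of the 45 peaks (11.1%), against 1.00% of random positions (permutation p = 0.0002, the smallest these draws can give, in a test chosen after the data were seen). With piRNA genes left out of the non-coding genes, 1.53 were expected (Fisher's exact adjusted p = 0.000214). The tRNA call was lost with replicate 3 left out (2 genes, Fisher's exact adjusted p = 0.297).

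The transcription factor lists held 1 gene with a reproducible peak in a promoter window. It was nhr-49 on chromosome I, with a signal value of 31.7 and its start 281 bp from the summit; 1 of 274 nuclear hormone receptor genes did not pass the test (Fisher's exact adjusted p = 0.795). None of 100 homeobox genes, 39 bHLH genes or 164 other transcription factor genes had one (Fisher's exact adjusted p = 1 for each). elt-2, which encodes a GATA factor of the intestine, had a peak in an intron, 1753 bp from its start (30.7). Among the other coding lists, 1 of 41 translation factor genes had a peak, eef-1A.2 (32.4; Fisher's exact adjusted p = 0.217). No gene had one among 144 neuropeptide, 24 pan-neuronal, 82 ribosomal protein, 228 collagen and cuticle, 57 muscle, 380 intestine, 107 germline, 83 histone and 62 heat shock genes (Fisher's exact adjusted p = 1 for each). With 17 coding genes carrying a peak, these tests could detect only large shares. By Fisher's exact test, the non-coding lists without a call were miRNA (2 of 261, cel-mir-53 and cel-mir-52, adjusted p = 0.217), snRNA (1 of 129, the SL2 spliced leader gene sls-2.1, adjusted p = 0.618), snoRNA (1 of 346, adjusted p = 0.99) and rRNA (0 of 22, adjusted p = 1).

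CEH-9 has a homeodomain, and the peaks were therefore searched for the homeodomain words TAATTA and TAATTG. They occurred at 9 of 45 reproducible peaks (20%, 95% interval 9.58 to 34.6), among them the peaks nearest to F20B6.9 and cest-16, and at 92 of 450 weak regions (20.4%; Fisher's exact test, p = 1, adjusted p = 1). Median GC content was 42.6% at the peaks and 38.5% in all weak regions, a difference that can lower words of A and T at the peaks. Weak regions matched on GC content, a set chosen after the data were seen, held the homeodomain words at 13.3% (Fisher's exact test, p = 0.256). The word GAGARAGA was more frequent at the peaks than at weak regions, at 14 of 45 (31.1%, 95% interval 18.2 to 46.7) and 26 of 450 (5.78%; Fisher's exact adjusted p = 1.18e-05). It was present at the peaks of F20B6.9, T10B10.11, cel-mir-53, zfp-1, pdk-1, mbk-2 and eef-1A.2, and at similar shares on X (7 of 22) and autosomes (7 of 23). The GATA word TGATAA was found at 2 of 45 peaks and 80 of 450 weak regions (4.44% and 17.8%; Fisher's exact p = 0.0195, adjusted p = 0.0781). The bHLH words (13.3% and 13.6%, adjusted p = 1), the NK-2 type words (4.44% and 8.89%, adjusted p = 0.655) and the control words ATTTAA and TTAAAT (11.1% and 19.1%, adjusted p = 0.457) and AATATT (11.1% and 16.2%, adjusted p = 0.692) did not pass Fisher's exact test. The GAGARAGA call was lost in the 45 strongest regions of replicate 3 (8.89% against 5.11%, Fisher's exact p = 0.294). In the 500 strongest pooled regions, a set chosen after the data were seen, the homeodomain words were less frequent than in weak regions (14% and 19.5%; Fisher's exact p = 0.00233), as were the control words.

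**Figure D2:**
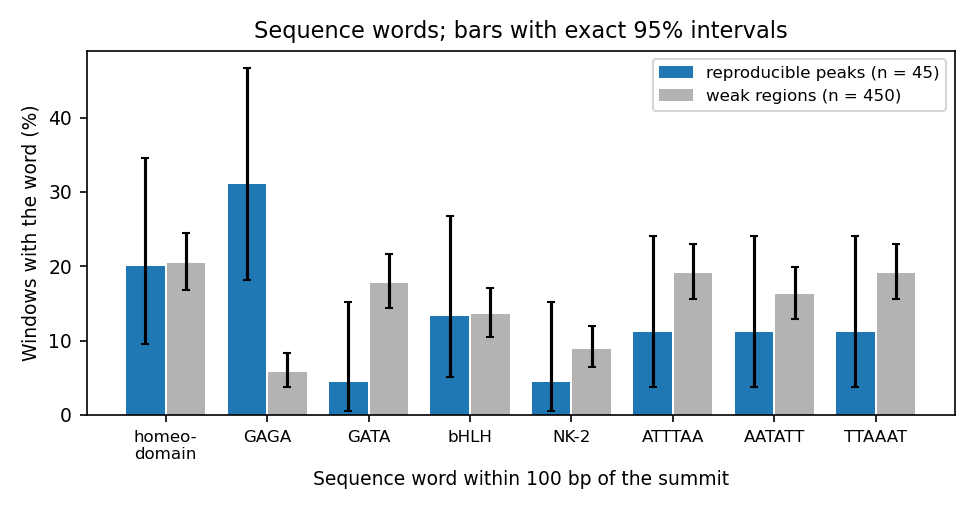
Share of windows (vertical axis, percent) with each sequence word within 100 bp of the summit, for the 45 reproducible peaks (blue) and 450 weak regions (grey), with exact 95% intervals. Only the GAGARAGA word stands apart, at 31.1% against 5.78%.

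Replicates were compared to measure how far the individual lists shared their strongest regions. Of the 1000 strongest regions of replicate 1, 43 (4.3%, 95% interval 3.13 to 5.75) lay within 200 bp of one of the 1000 strongest of replicate 3, against 0.391% in shifted lists (permutation p = 0.001, the smallest that 1000 shifts can give). The shifts do not separate sites shared through the ChIP from sites shared through the control that both lists were called against. Signal values of these 43 regions gave Spearman's rho of 0.158 across regions (permutation p = 0.311), and 0.254 over the 102 regions matched among the strongest 2000 (p = 0.0103). The reproducible set was derived from these lists, so its presence in them is given as counts. All 45 peaks had a region within 200 bp in replicate 1, at a median rank of 64, and 40 of 45 (88.9%) had one in replicate 3, at a median rank of 1854.5. Among the 45 strongest regions, 19 were found in replicate 1 and 8 in replicate 3. The ranks of replicate 1 count its mitochondrial regions, 16 of the 45 strongest, and 22 peaks were found among its 45 strongest nuclear regions. The X peak beside WBGene00014538 ranked 22 in replicate 1 and 1 in replicate 3, and that of nspc-17 ranked 6 and 3. The peak inside zfp-1 at 8795699 ranked 32 in replicate 1 and had no region within 200 bp in replicate 3. The peak at snt-4, a synaptotagmin family gene, ranked 4113 in replicate 1 and 13 in replicate 3.

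**Figure D3:**
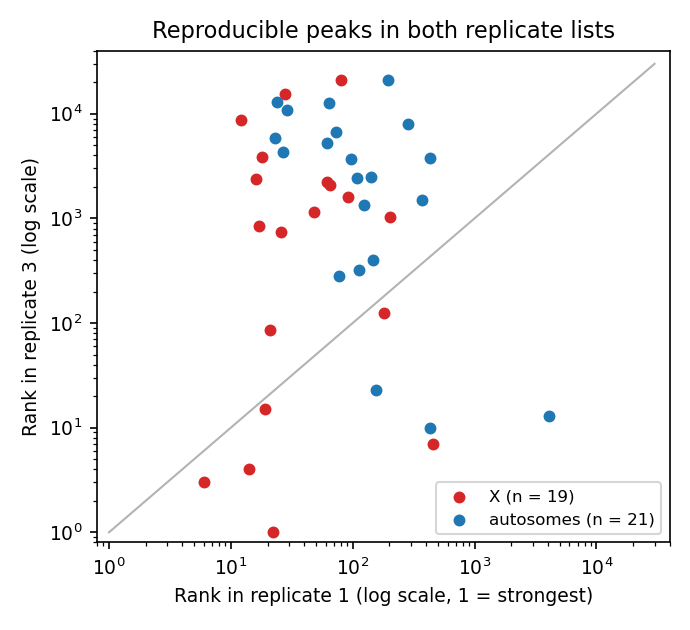
Rank of the 40 reproducible peaks matched in both lists, in replicate 1 (horizontal axis) and replicate 3 (vertical axis), both on log scales with 1 the strongest; red points are on X and blue points on autosomes. Most points lie above the line of equal rank, with medians over all matched peaks of 64 in replicate 1 and 1854.5 in replicate 3.

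The loci named in the transgene were examined for ChIP signal. At ceh-9 (WBGene00000434, chromosome I, 565284 to 566588), the pooled list held 0 regions within 20 kb, where random windows held a median of 4, and 2.97% of random windows were also empty. Replicate 1 and replicate 3 each held 1 region there, against a median of 12. As few regions occurred in 0.7% of random windows in replicate 1 and 0.84% in replicate 3. Within 5 kb, where random windows of the pooled list held a median of 1, 36.4% of them were also empty, and 5.64% and 6.95% in replicates 1 and 3. No region was called between 550650 and 590039 in replicate 1 or between 551074 and 589005 in replicate 3. That interval holds ptr-21, lpr-1, ceh-9, grl-16 and other genes. Near unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935), the pooled list held 4 regions, the strongest with a signal value of 19.6 at the percentile 72.6 of random windows. There were 18 regions near unc-119 in replicate 1 and 22 in replicate 3, and as many occurred in 7.14% and 1.03% of random windows.

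**Figure D4:**
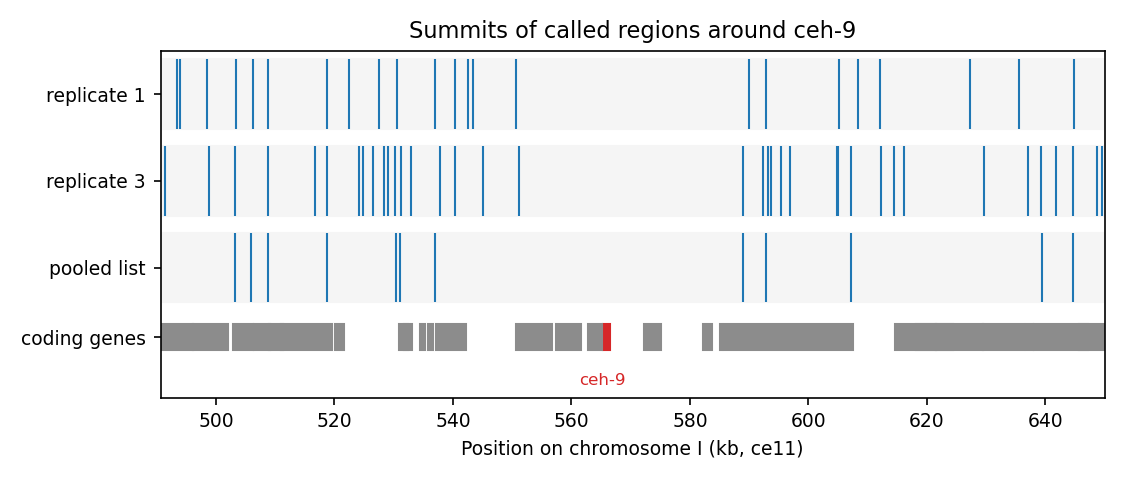
Summits of called regions (blue lines) in replicate 1, replicate 3 and the pooled list along chromosome I (horizontal axis, kb on ce11), with protein-coding genes as grey boxes and ceh-9 in red. No summit of the 3 lists lies between those at 551074 (replicate 3) and 588986 (pooled list).

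On build ce10 the authors' reproducible set had 48 peaks, 22 of them on X, and the pooled list had 9525 regions. The highest signal value was 73.4 on ce10 and 72.9 on ce11, and values of equal rank differed by at most 3.83% in the pooled lists. No peak was matched between builds.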

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

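The tests of the X share of weak regions, of the motif's presence and of the interval's length were chosen only after the results were seen, and the planned X share of replicate 3 was taken up as a test of an explanation only then. In replicate 1, 30 regions were called on the mitochondrial chromosome, and replicate 3 and the pooled list had 0. Comparisons with genes and chromosomes do not use them, but the replicate 1 ranks and the replicate overlap include them. They included 9 of the 10 strongest regions of replicate 1, with signal values up to 80.1. No explanation for them was tested.

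The X chromosome held 22 of the 45 reproducible peaks. A higher copy number or better mappability of X could raise the whole list. The X share of the weak regions was 19.7% (95% interval 18.7 to 20.8), slightly above the 17.7% given by chromosome length. At pooled ranks 46 to 200 it was 23.2%. A general rise on X need not change weak and strong regions by the same amount. The weak share therefore cannot decide whether either adds to the 48.9% among the reproducible peaks. A candidate explanation is that part of the peaks lie at sites where the dosage compensation complex loads onto X, which share the 12-base X recruitment motif TCGCGCAGGGAG. With up to 2 mismatches, 7 of 22 X peaks (31.8%) held it, against 7 of 1034 weak X regions (0.677%, Fisher's exact test, p = 1.88e-09). Only 3 of 111 X regions at pooled ranks 46 to 500 did (2.7%, Fisher's exact test, p = 0.0642). Of the 3 exact copies of the motif on X, 1 had its centre 55.5 bp from a reproducible summit and 2 lay over 38 kb from any. In these 7 peaks the motif lay a median of 24.5 bp from the summit (permutation p = 0.0159, a test fixed before its result was seen). Of the 9 X regions among the 45 strongest of replicate 3, 3 held it (against weak X regions, Fisher's exact test, p = 5.19e-05). These were 3 of the same 7 peaks, and 6 of the 7 were matched among the 1000 strongest regions of replicate 3. At these peaks the motif was therefore not confined to replicate 1. Away from them, 0 of the other 6 X regions held it (0%, 95% interval 0 to 45.9), too few to tell whether it marks further strong X regions of replicate 3. A tie of the X excess to the ranking of replicate 1 stays open, since X held 20% of the 45 strongest regions of replicate 3 (95% interval 9.58 to 34.6), and whether the tagged protein, the antibody or open chromatin brings these sites into the list was not tested.

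The interval without called regions at ceh-9 was 39.4 kb long in replicate 1 and 37.9 kb in replicate 3, with ends that differed by 424 and 1034 bp. Low mappability is argued against by the 94.4% of 36-base words in it that are unique in the genome, at the percentile 46.8 of 1000 random intervals. Of the 13 intervals at least as long in replicate 1, ceh-9 lay in the only 1 with 90% or more unique words. Its own length was the cut, and it was the shortest of the 13. Intervals just below that length were not counted, and the count was made in replicate 1 only. Whether it is an ordinary long interval therefore stays open. Intervals at least as long made up 0.904% of the genome in replicate 1, 0.871% in replicate 3 and 5.14% in the pooled list, for its interval of 51.99 kb. Extra copies of the transgene, if present in the control that both replicates were called against, could raise the local background and remove calls, and this stays open because control reads were not analysed here and the replicates share that control.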

How the results depend on the processing

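Of the alternatives, those with the 500 strongest pooled regions, GC-matched regions, nuclear chromosomes only, no piRNA genes, random positions, protein-coding starts against weak regions and all for GAGARAGA were chosen after seeing the data. The replicate overlap and the X share with both replicates in use kept their direction and side of the threshold throughout. The promoter share was 68.9% with 2000 bp upstream, 47.8% in the stronger peaks, 33.3% with protein-coding starts, against random positions or weak regions, and 40% to 51.1% with 1 replicate left out, all no longer past the threshold. With 1 replicate left out, the X share was 20% to 48.9%, the GAGARAGA share 8.89% to 26.7%, the number of gene lists with a call 0 to 2, the ceh-9 percentile 1.23 to 2.17 (past the threshold, unlike 2.97) and the unc-119 percentile 39.8 to 81.8. The ceh-9 percentile was 36.4 within 5 kb and 75.4 within 50 kb, and that of unc-119 45.96 within 5 kb. Spearman's rho was 0.254 with 2000 regions (now past the threshold) and −0.055 over reproducible peaks. The homeodomain share turned above its background within 50 bp (13.3%), in the stronger peaks (26.1%) and against GC-matched regions (20%), none past the threshold, and was below it in the 500 strongest regions (14%, past the threshold), where 5 gene lists had a call. The stricter set had 23 peaks by its construction. Apart from that, the cause was not tested. Depth and control reads were not analysed here, which limits what a missing region can show. No paired analysis was possible because there is 1 group.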

Other observations

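The tests of the 500 strongest pooled regions and of tRNA genes against GC-matched regions were chosen only after the tRNA result was seen. In this wider set, the lists that passed Fisher's exact test were tRNA genes (30 of 634, adjusted p = 9.88e-14), miRNA genes (9 of 261, adjusted p = 0.00251), snoRNA genes (10 of 346, adjusted p = 0.00314), ribosomal protein genes (5 of 82, adjusted p = 0.00649) and snRNA genes (5 of 129, adjusted p = 0.0145). The miRNA genes included cel-mir-52, cel-mir-53, cel-mir-54, cel-mir-55 and cel-mir-56. The ribosomal protein genes were rpl-20, rpl-35, rpl-12, rps-19 and rpl-24.2, and the snRNA genes included the spliced leader genes sls-2.1, sls-2.2 and sls-2.4. Homeobox genes did not pass (2 of 100, unc-42 and lim-9, Fisher's exact adjusted p = 0.416). X held 26.6% of these 500 regions.

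The tRNA genes beside the reproducible peaks were set against 2 technical explanations. GC content is argued against, since 6 of 450 weak regions matched on GC content (1.33%) lay in a tRNA window, against 5 of 45 peaks (Fisher's exact test, p = 0.00153). High transcription of any kind may account for the pattern. Among ribosomal protein genes 0 of 82 had a reproducible peak, but only 0.0698 were expected, so a count of 0 was likely either way and the bound set beforehand decides nothing, while 5 of 82 had a region among the 500 strongest. No biological explanation was tested.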
